A study of Homo sapiens with 8 samples.

How the data were processed

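RNA of Kasumi-1 cells was measured on Illumina bead arrays with biotin-labelled cRNA, per the labels' protocols, in 8 samples: 4 with mismatch siRNA (siMM) and 4 with RUNX1/ETO siRNA (siRE), 1 of each at 48, 96, 168 and 240 h. The siRNA groups come from the sample characteristics, and the times from the sample titles and source names. The values are the authors' processed table, on a scale read here as log2 because their range of 3.89 to 14.36 would exceed a 16-bit scanner on a natural or decimal log scale. Per the submitters' processing notes the authors used lumi, with no version given; background handling, filters and the exact transformation are not given in the sources used here. The sorted values of the 8 arrays differed by at most 0.0235, as after quantile normalization, so no further normalization was applied, and a shift shared by most transcripts of a sample is not visible in such values. The scale (log2 or variance-stabilised) stays unknown, the values were not centred per probe, and a variance-stabilised scale would compress differences of dim probes. A second, non-normalized table with 16 columns of signals and detection p-values was not used, because no label ties its columns to samples. The analysis planned before the data were examined had started from that table, so its background correction, detection filter and offsets were not run, and the authors' values took their place.

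Background was estimated from the values themselves: the mode of all values was 5.22, and the cut-off of 5.90 lies above it by the 90th percentile of the distances of lower values from the mode. It was set after the distribution was seen and before any test. A probe was tested if it exceeded the cut-off on at least 2 of the 8 arrays, which left 14644 of 47230 probes. Of all probes, 30112 had 1 gene symbol in the platform annotation, 8 had several and 17110 had none. The Entrez numbers of 30073 were in the RefSeq table of assembly GRCh38.p14, which changed 0 symbols; chromosomes are from that table. Of the tested probes 3147 had no single named gene. A gene was represented by its tested probe with the highest mean, for 8830 genes, and 0 genes had called probes of opposite direction. Where a gene was not above the cut-off on any array of an arm, a bound is given: the brighter arm's mean against the dimmer arm's mean with each array set to at least the cut-off.

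Tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The main fit had siRNA and time point as factors, with 3 residual and 8.16 prior degrees of freedom, so its error is the spread of the siRNA effect between times. The time point given in the labels pairs the arrays. Deviations from the arm means of arrays of the same time correlated at 0.375, 0.292, 0.212 and 0.0724 for 48, 96, 168 and 240 h, the last below 0.1. Arrays of different times correlated between -0.320 and 0.198. The siMM array of 240 h correlated more with the siRE array of 48 h (0.1375) than with its own pair. The change with time was the siRNA by day interaction (days 2, 4, 7 and 10; 2 residual degrees of freedom) and the control trend was the siMM slope in a fit with a slope per siRNA (4 residual degrees of freedom). Differences at single times were given without a test. Each of the 8 sample titles has a letter of its own whose meaning is not stated, and the labels name no batch. If the letters mark array positions or batches, these cannot be told apart from siRNA, since all letters of siMM come before those of siRE in the alphabet.

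The 28 gene lists were fixed before the data were examined, from general knowledge: the siRNA target, granule, maturation, transcription factor, stem cell, t(8;21), cell cycle, ribosome, interferon, p53, cholesterol, stress, energy, lysosome, antigen presentation, cytokine, adhesion, apoptosis, repair and chromatin genes, and markers of 5 other lineages. Of their 712 different genes 442 were tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists. With the correlation estimated per list, 0 lists were called (11 with the preset); the siRNA target list, with 2 genes, gave no estimate. The test fry asks whether a list's genes move on balance one way, or change in either direction, and compares no list with other genes. Among genes past the threshold with 1 direction at all 4 times, the text names the 12 with the largest mean rise. It also names the 12 with the largest mean fall, of which 1 is left out. Named too are up to 4 members per list, past the threshold first, and the 6 largest slopes each way (3 each way by p where none passed). RUNX1T1 and RUNX1 probes that passed the filter are named and the others counted. Other genes are said to be named after their values were seen.

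On simulated data with the measured means and spread and 14644 probes, the main fit recovered 94% of probes changed by 1 and 100% of those changed by 2 on the log2 scale, with 13 false among 207 calls. The interaction recovered 9% of slopes of 0.2 and 97% of slopes of 0.4 per day, with 2 false among 108 calls. For the control trend the shares were 38% and 100% where the measured time effects were kept, with 21 of 159 calls outside the changed probes. Those 21 need not be false, since probes given no simulated slope kept their measured time course. Without the time effects the shares were 83% and 100%, with 8 false among 191 calls. Camera with the preset correlation called a simulated list of 30 genes shifted by 0.5 and 0 of 27 others. With an estimated correlation it missed that list (camera adjusted p = 0.0661). The simulated probes were drawn independently. The called lists with an estimate had correlations from 0.053 (myeloid transcription factors) to 0.632 (ribosome biogenesis and MYC-linked genes). The simulation therefore cannot say which setting is right for the measured lists.

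Alternatives were the fit without the time block, no filter, an intensity trend with a robust prior, array quality weights, each time pair left out, log2 of the day, later against earlier pairs, the siMM arrays alone, camera with estimated correlation, fry, all probes of a list, and a 1.5-fold minimum. Added after the data were seen were a filter of 4 arrays, a cut-off from the 95th percentile, cyclic loess on the deposited values, equal medians over probes above background, values below background set to the cut-off, and an estimated correlation for camera on the slopes of the lists.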

Results

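Kasumi-1 is an established human acute myeloid leukaemia line with the t(8;21) translocation, which joins the gene of the transcription factor RUNX1 to RUNX1T1, the gene of the corepressor ETO. The cells were electroporated with 200 nM of an siRNA against the RUNX1/ETO fusion transcript (siRE) or of a mismatch siRNA (siMM), and RNA was read on Illumina bead arrays at 48, 96, 168 and 240 h, after 1, 1, 2 and 3 electroporations. There were 8 arrays, 4 per siRNA, with 1 array per siRNA and time. A mean ± SD below is therefore taken over the 4 times of an arm, no time point has a replicate of its own, and the number of arrays limits the precision. Nothing in the labels says whether the times of an arm came from separate cultures, so the p-values measure the spread between these arrays. Values are the authors' normalized values on a log scale, treated as log2. Whether that scale is plain log2 or the variance-stabilised scale of the lumi package is not given in the sources used here. A fold below holds only for plain log2.

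The first question was whether the siRNA lowered its target. RUNX1T1 fell from 8.87 ± 0.26 in siMM to 7.48 ± 0.26 in siRE (SD, n = 4 arrays each) at its brightest probe (ILMN_1812795, chromosome 8). The change of -1.38 (SE 0.13, limma adjusted p = 0.000197) was 2.61-fold and left 38.4% of the control signal. It was -1.34, -1.43, -1.29 and -1.47 at 48, 96, 168 and 240 h. Of the other 4 RUNX1T1 probes, 3 did not pass the background filter, and ILMN_1724669 read 5.51 in siMM and 5.80 in siRE, a difference of 0.28 (limma adjusted p = 0.261). RUNX1 itself (ILMN_1801504, chromosome 21) read 8.56 ± 0.28 and 8.15 ± 0.15, a difference of -0.42 that did not pass (limma adjusted p = 0.146), and its other 2 probes did not pass the filter. Which part of the fusion or of the normal transcripts each probe reads is not given in the sources used here.

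**Figure D1:**
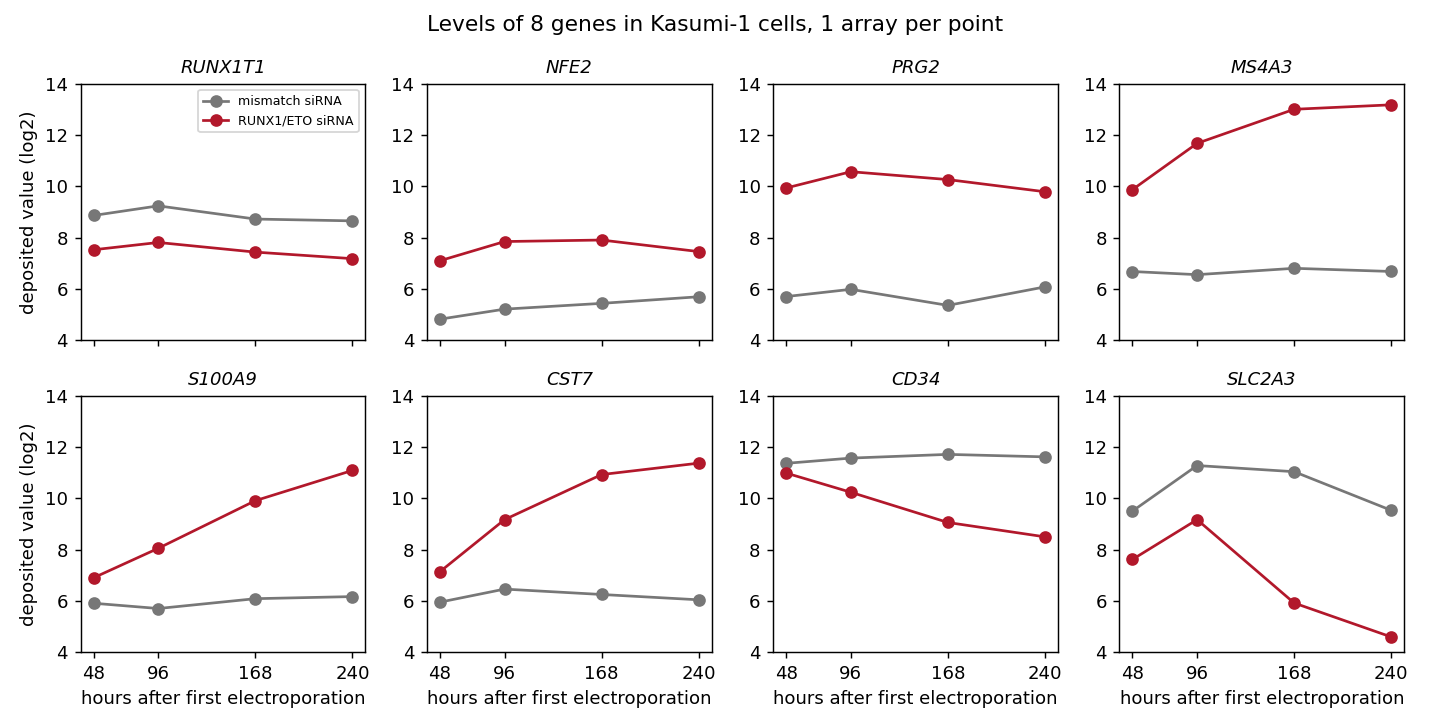
Deposited log2 value (vertical axis) against hours after the first electroporation (horizontal axis) for 8 genes, with grey points for mismatch siRNA and red points for RUNX1/ETO siRNA, 1 array per point and no error bars. RUNX1T1 was lower in siRE at each time by 1.29 to 1.47, while the difference of S100A9 went from 0.99 at 48 h to 4.92 at 240 h.

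The main comparison asked which transcripts differed between siRE and siMM over the 4 times. MS4A3, a membrane protein of myeloid progenitors, rose most, from 6.68 ± 0.10 to 11.93 ± 1.53, by 5.25 (SE 0.41, limma adjusted p = 8.9e-05). BPI, a bactericidal protein of neutrophil granules, rose by 4.51 (SE 0.53), PRG2, the eosinophil major basic protein, by 4.36 (SE 0.18), and CST7, an inhibitor of cysteine proteases, by 3.47 (SE 0.51). NKG7, a granule membrane protein known from cytotoxic lymphocytes, rose by 3.34 (SE 0.47) and CEACAM6, a granulocyte adhesion protein, by 3.14 (SE 0.24). SRGN, the proteoglycan core of secretory granules, rose by 3.02 (SE 0.31), S100A9, a calcium-binding protein of neutrophils and monocytes, by 3.02 (SE 0.46), CD24, a surface glycoprotein, by 2.94 (SE 0.27), and LYZ, lysozyme, by 2.94 (SE 0.46). The probe annotated to RNASE2CP rose by 2.58 (SE 0.23). RNASE2 is a near-identical copy, so which gene the probe reads is uncertain. PRKCD, a protein kinase, was not above background on any siMM array and was at least 2.63-fold higher in siRE. These 12 genes were higher at all 4 times, with limma adjusted p between 9.53e-07 and 0.00389. The SD within siRE was large where the difference grew with time. A dimmer LYZ probe rose less, by 1.18, and did not pass (limma adjusted p = 0.0675). The calls of S100A9 (2.97) and LYZ (2.94) ended with values below background set to the cut-off (limma adjusted p = 0.0528 for both).

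SLC2A3, a glucose transporter, fell most, from 10.34 ± 0.95 to 6.83 ± 1.99, a change of -3.51 (SE 0.47, limma adjusted p = 0.0014). Its near-identical copy SLC2A14 may share the probe. TSPAN7, a tetraspanin, changed by -2.35 (SE 0.31), FAM171A1 by -2.27 (SE 0.33), MTSS1, an actin regulator, by -2.16 (SE 0.20), and MDK, the growth factor midkine, by -2.14 (SE 0.25). MMP28, a secreted metalloprotease, was not above background on any siRE array and was at least 2.98-fold lower there. PTK2, focal adhesion kinase, changed by -1.91 (SE 0.28), and CD34, the surface marker of haematopoietic progenitors, by -1.87 (SE 0.35). CKB, a creatine kinase, changed by -1.86 (SE 0.25), EGFL7, a secreted protein with EGF-like domains, by -1.86 (SE 0.30), and TCEA3, an elongation factor, by -1.79 (SE 0.20). These 11 genes were lower at all 4 times, with limma adjusted p between 4.99e-05 and 0.00958. The call of CD34 ended without the 96 h pair of arrays (-2.05, limma adjusted p = 0.0523) and without the 168 h pair (-1.61, limma adjusted p = 0.0905). Of 5 CD34 probes above background, 2 did not pass (-0.63 and -0.44, limma adjusted p = 0.129 and 0.0787). MTSS1 and TCEA3 were above background in siRE at 48 h alone; with values below it set to the cut-off they stood at -1.81 and -1.28, and the call of CD34 ended (limma adjusted p = 0.0704). With an intensity trend and a robust prior, calls ended for BPI, CST7, NKG7, SRGN, S100A9, LYZ, SLC2A3, TSPAN7, FAM171A1, PTK2, CD34 and EGFL7, at limma adjusted p between 0.0585 and 0.194.

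In all, 889 of 14644 probes above background passed, 479 higher and 410 lower in siRE, and 3328 passed at an unadjusted p under 0.05 (limma). They gave 332 genes higher and 295 lower, of which 116 and 70 differed by 2-fold or more. Without the time block, 530 probes passed, 315 higher and 215 lower. Setting values below background to the cut-off left 464, 278 higher and 186 lower. The count was 310 without the 96 h pair and 251 without the 168 h pair, and 231 probes were lower without the 240 h pair. Leaving out a pair leaves fewer arrays and residual degrees of freedom. A call can therefore end at an unchanged or larger estimate.

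With 1 array against 1, differences at single times are given without a test. At 48 h, 87 probes were higher and 40 lower in siRE by 2-fold or more, at 96 h 169 and 82, at 168 h 292 and 240, and at 240 h 514 and 725. MS4A3 stood at 3.19 and PRG2 at 4.23 already at 48 h, whereas CD34 stood at -0.38. Across 14644 probes, which are not independent replicates, the differences at 2 times correlated with Pearson's r between 0.361 (48 and 240 h) and 0.662 (168 and 240 h). By rank the correlation was lower, with Spearman's coefficient at 0.224 and 0.532 for the same pairs of times.

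**Figure D2:**
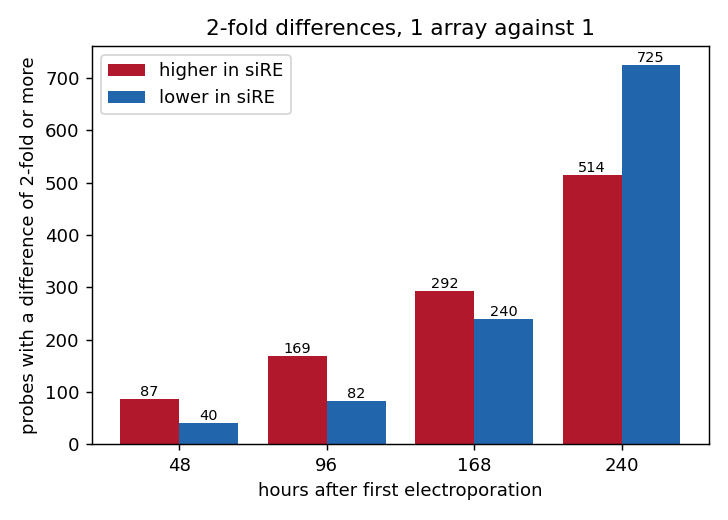
Number of probes that differ by 2-fold or more (vertical axis) between the siRE and siMM array of each time (horizontal axis, hours after the first electroporation), red for higher and blue for lower in siRE. Probes higher went from 87 at 48 h to 514 at 240 h and probes lower from 40 to 725.

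**Figure D3:**
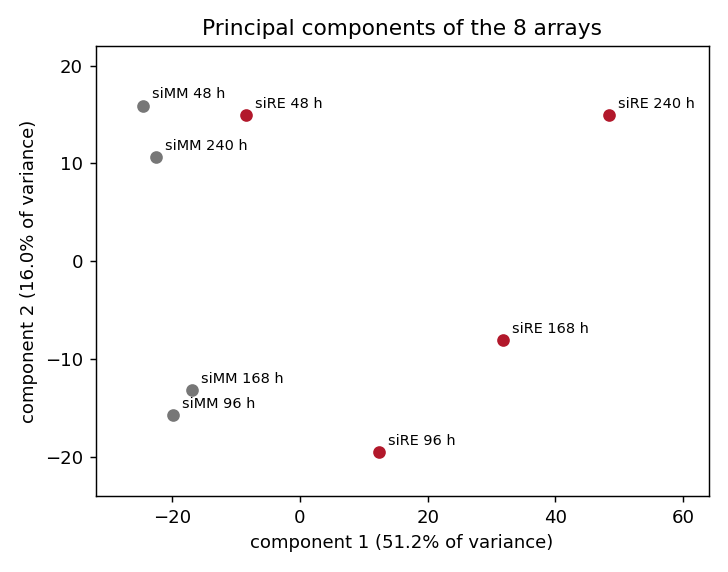
Each point is 1 of the 8 arrays on the leading principal components of the probes above background (horizontal axis component 1, 51.2% of the variance; vertical axis component 2, 15.98%), grey for siMM and red for siRE. The siRE arrays lay at -8.50, 12.39, 31.83 and 48.35 on component 1 at 48, 96, 168 and 240 h, and the siMM arrays between -24.61 and -16.96.

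The gene lists asked which groups of genes differed between siRE and siMM, as groups. Unless the listed number is given too, the number of genes stated for a list counts its tested members alone. Of 13 granule proteases and proteins above background, 8 were higher and 0 lower (11 higher adjusted over the list alone). Their median difference was 2.26 (camera adjusted p = 3.7e-13, and adjusted p = 0.675 with an estimated correlation). Over the alternative runs the median of the list ranged from 1.49 to 2.52. Beside MS4A3, PRG2, CST7 and SRGN, genes named after their values were seen show that the list did not move as a whole: CTSG, cathepsin G, rose by 2.26, while MPO, myeloperoxidase, stood at -0.11 and ELANE, neutrophil elastase, at 0.48 (limma adjusted p = 0.648 and 0.125). Of 32 granulocyte and monocyte maturation markers listed, 18 were tested. Of these, 7 were higher and 0 lower (10 higher adjusted over the list alone), with a camera adjusted p = 1.6e-05, and adjusted p = 0.675 with an estimated correlation. S100A9 rose by 3.02, S100A8, its partner, was at least 4.05-fold higher, TYROBP, a signalling adaptor of myeloid receptors, rose by 2.27 (SE 0.35), and AIF1, a monocyte protein, by 1.40 (SE 0.23). The call of S100A8 ended without the 96 h pair (limma adjusted p = 0.0581), without the 168 h pair (limma adjusted p = 0.153) and without the time block (limma adjusted p = 0.0717), and with values below background set to the cut-off (limma adjusted p = 0.15). It also ended, like that of TYROBP, with an intensity trend and a robust prior (limma adjusted p = 0.262 and 0.133).

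Myeloid transcription factors moved in both directions, with 5 of 12 higher and 2 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.00653 upwards, and adjusted p = 0.675 with an estimated correlation). NFE2, a basic leucine zipper factor known from erythroid and megakaryocyte cells, was at least 3.19-fold higher, IRF8, a factor of monocyte development, rose by 1.84 (SE 0.15), and CEBPE, a factor of late granulocyte development, by 1.58 (SE 0.14). JUN, a subunit of AP-1, changed by -1.36 (SE 0.18), a call that ended without the time block (limma adjusted p = 0.096). Of 23 lysosome genes, 5 were higher and 0 lower (10 higher adjusted over the list alone; camera adjusted p = 2.0e-06, and adjusted p = 0.675 with an estimated correlation). LAPTM5, a lysosomal membrane protein of blood cells, rose by 1.70 (SE 0.21), LAMP2 by 1.13 (SE 0.24), CTSD, cathepsin D, by 0.94 (SE 0.15) and GRN, progranulin, by 0.88 (SE 0.17). LAMP2 and GRN lost their calls without the 96 h pair (1.06 and 0.92, limma adjusted p = 0.127 and 0.0702) and without the 168 h pair (0.95 and 0.90, limma adjusted p = 0.158 and 0.0804). Calls also ended for GRN without the time block (limma adjusted p = 0.125) and for LAMP2 with an intensity trend and a robust prior (limma adjusted p = 0.0645) and with values below background set to the cut-off (limma adjusted p = 0.0853).

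Of 24 stem and progenitor genes listed 10 were tested, of which 3 were lower and 0 higher (6 lower and 1 higher adjusted over the list alone). The median was -0.43, or -0.25 with genes near background at their bound, with a camera adjusted p = 0.0416, and adjusted p = 0.675 with an estimated correlation. They were CD34, ANGPT1, the ligand angiopoietin 1, at -1.65 (SE 0.19), and BAALC, a gene of immature leukaemic blasts, at -1.47 (SE 0.20); GATA2 stood at -0.79 (limma adjusted p = 0.0509). The list lost its call without the 96 h pair (median -0.37, camera adjusted p = 0.0761), without the 168 h pair (median -0.41, camera adjusted p = 0.0666), and with the stricter filters on background (camera adjusted p = 0.117 and 0.115). CD34 also lost its call without either pair (-2.05 and -1.61), and GATA2 passed without the 48 h pair (-1.04, limma adjusted p = 0.0108). GATA2 also passed with no filter, the stricter filters on background, an intensity trend and a robust prior, and array weights (limma adjusted p between 0.032 and 0.0461), at -0.69 with array weights and -0.79 in the others. The list (median -0.24, camera adjusted p = 0.295) and CD34 (limma adjusted p = 0.0704) lost their calls with values below background set to the cut-off, where GATA2 stood at -0.34.

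The medians of G1/S, G2/M and ribosome biogenesis genes stood at 0.06, 0.05 and -0.02 at 48 h and at -0.63, -0.50 and -0.79 at 240 h. Camera called the slopes of these 3 lists with the preset correlation (adjusted p = 5.5e-05, 0.000497 and 2.0e-07) and not with an estimated correlation (adjusted p = 0.753, 0.753 and 0.609). Over the 4 times, of 29 G1/S genes, 4 were lower and 0 higher (14 lower adjusted over the list alone; median -0.32, camera adjusted p = 1.5e-05, and adjusted p = 0.675 with an estimated correlation): CCNE1, cyclin E1, at -0.82 (SE 0.22), CHAF1B at -0.72 (SE 0.17), UHRF1 at -0.71 (SE 0.15) and CDC45 at -0.63 (SE 0.17). Of 38 G2/M genes, 2 were lower, CDK1 at -0.65 (SE 0.17) and PLK1, which was at least 1.05-fold lower, and 0 were lower adjusted over the list alone (median -0.28, or -0.27 with genes near background at their bound, camera adjusted p = 4.8e-05, and adjusted p = 0.675 with an estimated correlation). Of 29 genes of ribosome biogenesis and MYC-linked genes, 3 were lower and 0 higher (15 lower adjusted over the list alone; median -0.41, camera adjusted p = 1.3e-06, and adjusted p = 0.675 with an estimated correlation): PPAN at -0.85 (SE 0.20), RRP12 at -0.78 (SE 0.15) and PES1 at -0.57 (SE 0.14). The calls of all these single genes lay near the threshold (limma adjusted p between 0.012 and 0.0494). Each ended without the 96 h pair (CCNE1 -0.89, CHAF1B -0.65, UHRF1 -0.61, CDC45 -0.61, CDK1 -0.68, PPAN -0.81, RRP12 -0.75, PES1 -0.63, and PLK1, limma adjusted p between 0.0845 and 0.177) and without the 168 h pair (limma adjusted p between 0.0997 and 0.255), and each but RRP12 ended without the time block. Without the 240 h pair calls ended for CCNE1, CHAF1B, CDC45, CDK1, PLK1 and PPAN (limma adjusted p between 0.0755 and 0.143), and without the 48 h pair for PLK1 and PES1 (limma adjusted p = 0.0596 and 0.072). Calls also ended with no filter for CDC45, CDK1, PLK1 and PES1 (limma adjusted p between 0.0524 and 0.0856), with cyclic loess for CCNE1, CDC45 and CDK1 (0.051 to 0.054) and with an intensity trend and a robust prior for PLK1 (0.0931). They ended for CCNE1, CHAF1B, CDC45, CDK1, PLK1 and PPAN with values below background set to the cut-off (limma adjusted p between 0.0824 and 0.637). CHAF1B stood at -0.42 in that setting. In the main fit, dimmer probes of CCNE1, UHRF1 and CDK1 fell less and did not pass (-0.14, -0.41 and -0.43, limma adjusted p = 0.58, 0.18 and 0.2).

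Of 24 glycolysis and hypoxia genes, 2 were lower and 1 higher (11 lower and 1 higher adjusted over the list alone; median -0.40, camera adjusted p = 0.000526, and adjusted p = 0.675 with an estimated correlation). SLC2A3 and PFKP, the platelet form of phosphofructokinase (-0.79, SE 0.18), fell and NDRG1, a hypoxia-induced gene, rose by 1.01 (SE 0.18). This list also moved with time within each arm. Around the siMM mean its median stood at -0.37, 0.54, 0.20 and -0.33 at 48, 96, 168 and 240 h. Around the siRE mean it stood at 0.06, 0.66, -0.26 and -0.53. Of 21 chromatin regulators, 3 were lower and 0 higher (5 lower adjusted over the list alone; median -0.20, camera adjusted p = 0.0208, and adjusted p = 0.675 with an estimated correlation): TET1, a methylcytosine dioxygenase, at -0.91 (SE 0.16), UHRF1 at -0.71, and PRMT1, an arginine methyltransferase, at -0.50 (SE 0.13). The chromatin list lost its call without the 96 h pair (median -0.20, camera adjusted p = 0.0561). Of the single calls, those of PFKP (-0.88 and -0.65), TET1 (-0.84 and -0.83), UHRF1 (-0.61 and -0.68) and PRMT1 (-0.53 and -0.55) ended without the 96 h or the 168 h pair. That of NDRG1 ended without the 168 h pair (1.00), those of PFKP (-0.66) and PRMT1 (-0.45) without the 240 h pair, and that of PRMT1 without the 48 h pair (-0.47). All 5 ended without the time block, and that of PRMT1 with no filter and with cyclic loess (limma adjusted p = 0.096 and 0.0601). That of PFKP also ended with values below background set to the cut-off (limma adjusted p = 0.0748). The siRNA target list of 2 genes had a camera adjusted p = 0.00999, with RUNX1T1 lower, and lost the call when all probes were used (camera adjusted p = 0.193).

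**Figure D4:**
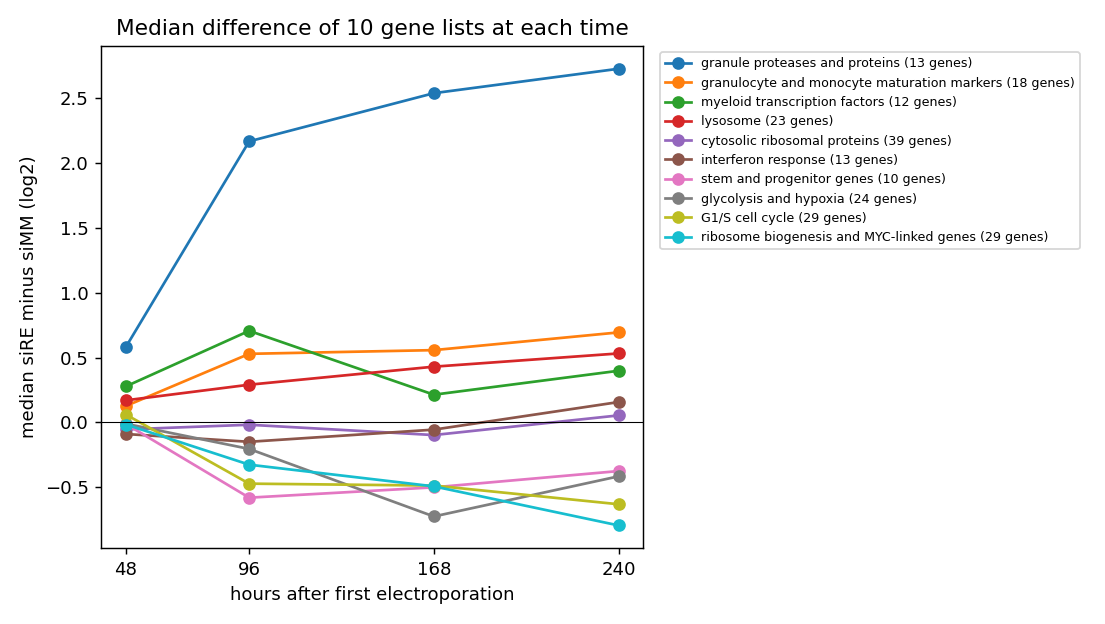
Median siRE minus siMM difference on the log2 scale (vertical axis) of 10 gene lists at each time (horizontal axis, hours after the first electroporation), 1 array against 1 per point, with the number of genes in brackets and no error bars. The median of granule genes went from 0.58 at 48 h to 2.72 at 240 h, and that of ribosome biogenesis genes from -0.02 to -0.79.

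The other 17 lists were not called by camera. Cytosolic ribosomal proteins had 0 of 39 members past the threshold (camera adjusted p = 0.947), oxidative phosphorylation 0 of 35 (0.512) and cholesterol synthesis 0 of 16 (0.911). Of 36 interferon response genes listed 13 were tested and 1 passed, IFITM3, an antiviral membrane protein, at -0.73 (SE 0.19, camera adjusted p = 0.911 for the list). Of 16 p53 targets, GADD45A, a stress-response gene, and TP53INP1 rose by 0.79 and 0.74 (camera adjusted p = 0.772). Of 18 genes of the unfolded protein and amino acid stress response, CALR, a chaperone, rose by 0.67 and ATF3, a stress-induced factor, fell by 0.66 (camera adjusted p = 0.512). Of 5 MHC class II genes, 1 passed, HLA-DRA at -0.86 (SE 0.22; camera adjusted p = 0.0601), and that list was called without the 48 h, 96 h or 240 h pair (camera adjusted p = 0.0426, 0.0423 and 0.0473) and with all probes of a gene (camera adjusted p = 0.00265). Over all 4 times it had adjusted p = 0.675 with an estimated correlation. Of 8 cytokines and chemokines, TNFSF10, the death ligand TRAIL, was at least 1.72-fold higher and CXCL8, the chemokine interleukin 8, changed by -0.95 (SE 0.15; camera adjusted p = 0.512). Of 13 adhesion and migration genes, CXCR4, a chemokine receptor, ICAM3 and CD47 rose by 2.38, 1.70 and 0.70, and 2 were lower, among them JAM3 at -1.12 (camera adjusted p = 0.772). Of 18 apoptosis regulators, CFLAR, a caspase-8 inhibitor, rose by 0.97 (camera adjusted p = 0.947), and of 20 DNA repair genes OGG1, the 8-oxoguanine glycosylase, rose by 0.90 (camera adjusted p = 0.376). Of 12 genes reported high in t(8;21) leukaemia, 4 were higher, among them PRG2 and IGFBP7, a secreted binding protein (1.79, SE 0.17), and 4 lower, among them RUNX1T1 and UBASH3B, a phosphatase (-1.25, SE 0.16; camera adjusted p = 0.774).

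Adjusted over the list alone, 5 genes of the t(8;21) list were higher and 5 lower, 2 and 2 p53 targets, 3 and 2 stress response genes, 2 and 1 cytokines, 4 and 4 adhesion genes and 5 and 4 apoptosis regulators. Of MHC class II genes 3 were lower. Of the other-lineage lists described next, adjustment over the list alone gave 1 higher and 3 lower mast cell, basophil and eosinophil genes and 1 higher and 1 lower B cell gene. For the remaining lists of these 17 it gave the same counts as over all genes. The median, the mean and the direction of camera differed in sign in 8 lists: t(8;21), cytosolic ribosomal, interferon, cholesterol, adhesion, apoptosis, erythroid, and mast cell, basophil and eosinophil genes (camera adjusted p of 0.772 or more).

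Markers of other lineages were mostly below background. Of 25 erythroid genes 4 were tested and CA2, a carbonic anhydrase also found outside red cells, rose by 0.94 (SE 0.20; camera adjusted p = 0.947). Of 19 megakaryocyte genes 3 were tested, and CAVIN2, a caveolar protein, was at least 1.09-fold lower (camera adjusted p = 0.495). Of 21 mast cell, basophil and eosinophil genes 7 were tested and PRG2 alone passed (camera adjusted p = 0.947). Of 18 B cell genes 3 were tested and CD24 rose (camera adjusted p = 0.341), and of 23 T and NK cell genes 7 were tested and NKG7 rose (camera adjusted p = 0.341). Among the genes named in these 17 lists, calls ended without the 96 h pair for IFITM3 (-0.92), GADD45A (0.84), TP53INP1 (0.83), ATF3 (-0.63), JAM3 (-1.19), CD47 (0.79), CFLAR (1.03), CA2 (0.83) and CAVIN2 (limma adjusted p = 0.123). Without the 168 h pair they ended for the same 9 genes (IFITM3 -0.56, GADD45A 0.63, TP53INP1 0.66, ATF3 -0.64, JAM3 -1.02, CD47 0.63, CFLAR 0.74, CA2 0.75, and CAVIN2 with limma adjusted p = 0.234), CALR (0.67) and HLA-DRA (-0.60), and without the 240 h pair for IFITM3 (-0.60), TP53INP1 (0.59) and HLA-DRA (-0.73). Without the time block, calls ended for IFITM3, TP53INP1, HLA-DRA, CXCL8 and CA2 (limma adjusted p = 0.0593, 0.139, 0.14, 0.118 and 0.127), and with an intensity trend and a robust prior for HLA-DRA and CAVIN2 (limma adjusted p = 0.062 and 0.0559). That of HLA-DRA also ended with array weights (limma adjusted p = 0.0502). Calls ended for IFITM3, TP53INP1, HLA-DRA, TNFSF10, JAM3, CFLAR, CA2 and CAVIN2 with values below background set to the cut-off (limma adjusted p between 0.0525 and 0.414).

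The next question was whether the difference between siRE and siMM changed from day 2 to day 10. Electroporations rose from 1 to 3 over these days, so a change with day cannot be told apart from repeated siRNA. FCER1G, the gamma chain of Fc receptors, gained 0.67 per day on the log2 scale (SE 0.04, limma adjusted p = 2.2e-05), and its mean difference did not pass (limma adjusted p = 0.0518). S100A8 gained 0.55 per day, CST7 0.53, NKG7 and S100A9 0.49 each and RETN, the secreted protein resistin, 0.48 (SE 0.04 to 0.05, limma adjusted p between 0.000111 and 0.000473). Part of these values lay below background, among them FCER1G on 3 and S100A8 and RETN on 4 siMM arrays. With values below background set to the cut-off, the slopes were 0.53 for FCER1G (limma adjusted p = 0.00701), 0.56 for S100A8 and 0.48 for RETN, and kept their calls. The difference of SLC2A3 changed by -0.45 per day (SE 0.07, limma adjusted p = 0.0136), that of SVOPL by -0.35 (SE 0.05), CD34 by -0.35 (SE 0.04), FAM171A1 by -0.33 (SE 0.04), TSPAN7 by -0.31 (SE 0.04) and PRDM8, a histone methyltransferase family member, by -0.30 (SE 0.04), with limma adjusted p between 0.00213 and 0.00552 for the last 5. The mean difference of SVOPL did not pass (limma adjusted p = 0.101). With values below background set to the cut-off, SLC2A3 (-0.30 per day), SVOPL (-0.33), CD34 (-0.35), FAM171A1 (-0.22) and PRDM8 (-0.30) lost their calls (limma adjusted p between 0.0535 and 0.304), and TSPAN7 kept its call (-0.30).

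The difference rose with day for 78 probes and fell for 61, 139 in all, and 2428 passed at an unadjusted p under 0.05 (limma). Of the 50 genes with a rising difference, 35 were also higher in the main comparison, and of the 43 with a falling one, 23 were also lower. By list, 5 granule genes, 4 maturation markers, 2 adhesion and migration genes and 1 lysosome gene rose with day, as did DDIT3, a stress-induced factor, and NKG7. CD34, CCNE1 and SLC2A3 fell with day in their lists. PRG2 (4.23, 4.59, 4.90 and 3.71 at the 4 times), NFE2, IRF8 (1.77, 1.61, 1.63 and 2.33) and CEBPE (1.84, 1.74, 1.42 and 1.31) had no called change with day (limma adjusted p = 0.656, 0.463, 0.458 and 0.389). The count depended on how time entered: with log2 of the day 64 probes passed and with later against earlier pairs 1, SLC2A3 being the only one of the 12 genes named here to keep its call (limma adjusted p between 0.056 and 0.187 for the others). Without the 48 h pair 94 probes fell. The count was 38 without the 96 h pair, when the call of SLC2A3 ended (-0.41 per day, limma adjusted p = 0.0686), 402 without the 168 h pair, 387 with an intensity trend and a robust prior (limma adjusted p = 0.188 for SLC2A3) and 219 with the stricter filter. With values below background set to the cut-off, 10 probes passed, 9 rising and 1 falling.

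In the mismatch control alone the question was what rises or falls steadily with time and repeated electroporation. By limma 0 probes passed, 271 did at an unadjusted p under 0.05 (146 rising, 125 falling), and the smallest adjusted p was 1. The 271 are less than the share of 0.05 of 14644 tested probes that chance would give, so they show no trend. The genes with the smallest p, none of which passed, were ZFAND2B (0.14 per day), HSF1, the heat shock factor (0.12), and PTDSS2, a phosphatidylserine synthase (0.12), upwards, and SHPRH (-0.13), C1orf74 (-0.11) and MINDY3, a deubiquitinase (-0.10), downwards. The fit of the 4 siMM arrays alone also gave 0 probes, with 332 at an unadjusted p under 0.05. These fits test only a straight-line slope, so a rise that returns by 240 h can be missed. SLC2A3, for example, read 9.50, 11.28, 11.04 and 9.53 in siMM at 48, 96, 168 and 240 h.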

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

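Of the tests in this part, those on other cell types, on the interferon list and on loss of signal at 240 h were chosen only after the result was seen.

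In 10 of 254 groups of 4 arrays 1 array lay far from the other 3, by Dixon's ratio above its 95% critical value, where chance would give 12.7. In siMM at 96 h these were PTK2 at 9.298 (nearest other array 8.885), IRF8 at 6.921 (6.367), BAALC at 7.611 (8.000), PPAN at 7.256 (6.937), IDI1 at 9.295 (8.858) and PFKP at 9.7 (9.025). In siMM they were also TCEA3 at 7.336 at 48 h (7.247), TYROBP at 6.688 at 168 h (6.247) and GP1BA at 6.297 at 240 h (5.937). In siRE at 48 h NOP56 stood at 11.81 (10.76).

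The siRE minus siMM difference changed with day for 78 probes upwards and 61 downwards by the interaction test. The slopes per day on the log2 scale were 0.6686 for FCER1G, 0.5455 for S100A8, 0.5253 for CST7, 0.4921 for NKG7, 0.4858 for S100A9 and 0.4791 for RETN. They were -0.4524 for SLC2A3, -0.3526 for SVOPL, -0.3488 for CD34, -0.3309 for FAM171A1, -0.3095 for TSPAN7 and -0.305 for PRDM8. With values below background set to the cut-off, the slopes were 0.5317 for FCER1G, -0.3015 for SLC2A3 and -0.2247 for FAM171A1, and 10 probes passed (9 rising, 1 falling). Of the 24 orders of the 4 pairs only the real one, 1, gave as many as 139 probes. The highest other was 88, in the reversed order, which nearly mirrors the real one, and the next was 17. Because of that mirror an order and its reverse were counted together, a change made after the result was seen, and the 12 that remain are too few for a share under 0.05.

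Exchanging the siRNA labels within time points gave 8 assignments: the real one, 1, gave 889 probes and the highest other 0, and 8 are too few for a share under 0.05. Without the time block, the real split of the 8 arrays into 4 and 4 gave 530 probes. Since time pairs the arrays, it was compared with the 8 splits that part the 4 pairs: 1, the real one, gave as many and the highest other gave 0, and 8 are too few for a share under 0.05. The other 27 of the 35 splits also gave 0 probes, but they divide the times unevenly. The test first written used all 35 splits and was narrowed after its result was seen.

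Of 13 granule genes 8 and of 18 maturation markers 7 were higher in siRE, among them S100A9 by 3.02, NKG7 rose by 3.34, and cells of another type in these cultures could carry such transcripts. On the 240 h siRE array 7 of 8 abundant genes of mature granulocytes and monocytes had no probe above background. They were S100A12, FCN1, CD14, FPR1, MNDA, CYBB and VCAN. S100A8, S100A9 and LYZ lay 4.24, 5.19 and 7.14 above it there. CSF3R, the other gene, lay 5.61 above background there and 4.47 in siMM. Of 8 T and NK cell genes 8 had no probe above background, with NKG7 5.48 above it. Both sets of 8 were picked after the result was seen. In the full lists, 18 of 32 maturation markers and 7 of 23 T and NK cell genes were tested. Their median differences at 240 h were 0.69 and 0.64. The values argue against cells rich in the silent transcripts, and cannot exclude other cells of these types. An interferon response stays open: the list's median of -0.0008559 decides nothing, since its members went both ways. Only 13 of its 36 genes were tested. Both arms received an siRNA, so a response shared by them is not visible in the difference. IFITM3, the only member past the threshold, stood at -0.73, and IRF7 stood at 0.60 without passing (limma adjusted p = 0.133). Adjusted over the list alone, 3 of 13 members rose with day. The comparisons with other cell types rest on the 240 h siRE array alone, where loss of signal stays open. How well the probes of the silent genes work was not tested, and a response of the Kasumi-1 cells to loss of RUNX1/ETO stays an open hypothesis.

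At 240 h 725 probes were lower and 514 higher in siRE by 2-fold or more, and loss of signal on that siRE array could give more falls than rises. The 725 probes had a median of -0.5663 at 168 h, on other arrays, where 89.2% of them were lower, so the direction was not limited to the 240 h pair. With probes split by mean level into 3 equal groups, from the dimmest to the brightest, the falls and rises were 297 and 184, 279 and 155, and 149 and 175. Falls thus did not outnumber rises among the brightest. The mean level included the siRE arrays, so a rise moved a probe towards the brightest group and a fall away from it. At 168 h the same groups gave 80 and 85, 85 and 97, and 75 and 110, again with fewest falls per rise among the brightest. The split by level therefore cannot decide the question. Loss of signal cannot be told apart from a larger siRNA effect at 240 h, since there is 1 array per siRNA at that time.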

How the results depend on the processing

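The filter of 4 arrays, the 95th percentile background limit, cyclic loess, equal medians, values below background set to the cut-off and the estimated correlation for list slopes were chosen only after the result was seen. The 889 probes kept their direction without each time pair and with array weights, cyclic loess and equal medians. For the time pairs this was nearly fixed in advance. Of the genes past the threshold, 329 of 332 higher and 292 of 295 lower had 1 direction at all 4 times. The time block, the filters and the trend cannot change the estimate of a single probe in this balanced design, only its p. The filters can change the median of a list. That of stem and progenitor genes went from -0.43 to -0.37 with the stricter filters. Of 69 named genes past the threshold, 41 kept their call without each time pair and 26 in every alternative run; 20 lost it without the time block and 18 with an intensity trend and a robust prior, and the cause was not tested. Without the time block 530 probes passed (315 higher, 215 lower). With values below background set to the cut-off 464 passed (278 higher, 186 lower) and 10 changed with day (9 rising, 1 falling), and some calls ended at an unchanged estimate. With the intensity trend and robust prior 656 were lower and 387 changed with day (166 rising, 221 falling). Without a filter 36 had a falling difference, with more probes tested, and with 4 arrays above background 219 changed with day (119 falling), with fewer probes tested. With log2 of the day 64 changed (47 rising, 17 falling), and with later against earlier pairs 1 (0 rising, 1 falling). Leaving out each pair gave 251 to 1175 probes in the main comparison (162 to 579 higher, 89 to 596 lower) and 38 to 402 for the change with day (29 to 169 rising, 9 to 233 falling). Of 28 lists 11 were called, 0 with an estimated correlation, 2 with fry directional and 14 with fry in either direction. The slopes of 8 lists lost their call with an estimated correlation. A 1.5-fold minimum gave 393 higher and 334 lower at 48 h, 739 and 707 at 96 h, 1150 and 1165 at 168 h, and 1724 and 2443 at 240 h. Scaling moved the median difference by at most 0.0209. The control trend had 0 probes in each limma setting run, with 204 to 1741 at an unadjusted p under 0.05. The 1741 came with no filter, where all 47230 probes were tested. Alternatives that start from the non-normalized table (background correction, offsets, median scaling, loess after it and detection filters) were not run. Signal near background limits dim genes: where an arm was not above it, a mean difference is given as a bound, and other differences and slopes of dim genes rest in part on values below background.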

Other observations

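The test of time in both arms was chosen only after the result was seen.

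With the arms averaged, several transcripts differed between times. ADM, the peptide adrenomedullin, read 6.04, 8.18, 7.80 and 6.12 in siMM and 6.18, 8.61, 6.71 and 6.23 in siRE at 48, 96, 168 and 240 h. BNIP3, a mitochondrial protein of cell death and mitophagy, read 10.89, 12.14, 11.38 and 10.25 in siMM and 10.76, 11.95, 10.14 and 9.04 in siRE. P4HA1, a collagen prolyl hydroxylase, and PFKFB4, a regulator of glycolysis, stood 0.96 and 1.30 above their arm mean at 96 h and -1.01 and -1.15 from it at 240 h, averaged over the arms. ANKRD37, KDM3A, a histone demethylase, NRN1 and TMEM45A were also highest at 96 h on average, as were CD69, an activation marker of leukocytes, and BHLHE40, a transcription factor. The arms differed in places: from 96 to 168 h CD69 went from 10.4 to 10.4 in siMM and from 9.58 to 8.78 in siRE, and ANKRD37 from 7.33 to 7.39 and from 7.30 to 6.22. TXNIP, a thioredoxin-binding protein, stood at -1.26, 0.59, 0.85 and -0.18. ADM, BNIP3, P4HA1 and ANKRD37 are members of the glycolysis and hypoxia list.

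By limma, with siRNA as a block and the 4 times as groups, 13 probes differed between times, 1856 did at an unadjusted p under 0.05, and the smallest adjusted p was 0.0379. With no filter 37 probes passed, and with an intensity trend and a robust prior 101. With 1 array per siRNA and time, a day effect of handling is not separated from time, and a contrast of times grouped by their measured values was tried and left out.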
